A study of Mus musculus with 12 samples.

How the data were processed

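RNA was sequenced from 12 libraries of the mouse B lymphoma line CH12F3-2A, 3 for each of 4 groups that combine a guide (Nop16 or non-targeting) with a state (24 h of CIT or none). Per the labels' protocols, a directional library kit was used on total RNA. HISAT2 2.2.1, StringTie 2.2.1 and the mouse build GRCm39 are named without roles in the submitters' processing notes. The annotation release, read length and strand setting of the counting are not given in the sources used here. The authors deposited 1 table of estimated counts for 56941 Ensembl genes, as whole numbers that are not scaled to library size. Low values were in excess at 4, with a shoulder at 8. The variance over mean between replicates, in 2 ranges of mean count in each group, had medians between 3.29 and 3.59. Its means lay between 4.75 and 6.10. These ratios also hold differences between replicates and bound the unit only loosely. From the excess at 4, 1 sequenced fragment seems to be worth about 4 counts, which the sources do not state. The deposited values were used as they stand, and a fit on values divided by 4 was added as an alternative after the data were seen.

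Symbols were matched through an annotation of an earlier mouse build, GRCm38, for 51948 of the genes. The other 4993 held at most 0.365% of a library's counts, and 131 shared a symbol with another gene. No coordinates are given, since the builds differ. All columns of the table belonged to the 12 libraries. Exon overlaps between genes were looked up in the same GRCm38 annotation. Total counts per library were 39690555, 44902683 and 47175155 without CIT and 43204940, 47080816 and 44997218 with CIT for the control guide. For the Nop16 guide they were 46748908, 41793002 and 42856595 without and 38866418, 48615177 and 41080153 with CIT. The 10 most abundant genes held 4.45 to 4.89% of the counts and mitochondrial genes 2.72 to 3.08%. Taken in units of 4 counts, the mean chi-square over genes above a minimum count was 2.19 to 3.26 per pair of replicates, with medians of 0.675 to 0.788. If 1 fragment is worth 4 counts, replicates thus differed by more than sampling noise. The labels call the replicates biological, and numbers shared between groups were not taken as pairs.

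Genes with too few counts were left out by filterByExpr, which kept 16794. Differences were tested with edgeR 4.0.16 (R 4.3.3) by a quasi-likelihood F test with TMM factors, which lay between 0.985 and 1.013. All 12 libraries entered 1 model with a mean per group, and the common dispersion was 0.015. The 5 contrasts were the guide difference in each state, the CIT response with each guide, and the difference between the CIT responses (the interaction). Adjusted p is by the Benjamini-Hochberg method over all tested genes, and a gene was called at an adjusted p under 0.05. Levels are counts scaled to library size (CPM) with the SD over 3 libraries, and log2 differences carry the model's SE. A fold against a group at or under 12 counts in all, 3 fragments at 4 counts each, is given as a lower bound against that floor, which covers counting error only.

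The choices in this paragraph were made before the data were examined. The 26 gene lists held 729 distinct genes and covered immunoglobulin chains, the switch recombination machinery, regulators of germline transcription with other transcription regulators of B cells, CD40, IL-4 and TGF-β targets, ribosome biogenesis, ribosomal proteins, p53 and MYC targets, and PRC2 with H3K27 demethylases. They also covered S phase, mitosis, the integrated stress response, the unfolded protein response, interferon response, plasma cell, B cell identity, glycolysis, cholesterol synthesis, mitochondrially encoded and immediate early genes, and markers of T cells, macrophages, fibroblasts and erythroid cells. Lists with at least 5 tested members, 24 of them, were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over 120 pairs of list and contrast, and again with an estimated correlation and with fry. Genes named in the text were Nop16 and the heavy chain constant genes, the 10 largest called differences each way with at least 5 CPM in the higher group and no overlap between the 3 libraries of each group, gene model names left out, and for each list up to 2 called members with the largest change each way, or the 2 with the smallest p where none was called. For the interaction no separation of libraries was asked for. A gene named in one contrast could be named in any other. Some genes that these rules take in are not reported here.

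Where a list had 5 or fewer called members one way, others among them were named after their values were seen. Alternatives were RLE size factors, no low-count filter, a stricter filter of 5 CPM in 3 libraries, the replicate number as a block, only the groups compared, DESeq2 1.42.0 (with a local dispersion trend, to which it fell back), a 1.5-fold minimum and leaving out each library in turn. Library totals without TMM, counts divided by 4 and a comparison over genes called in either guide contrast were added after the data were seen. The pipeline was tested on simulated counts with 200 genes changed by known folds. It recovered 44.8% of 1.25-fold, 74.6% of 1.5-fold and 81.8% of 2-fold changes for the unstimulated guide contrast over 13303 genes, with 12 unchanged genes called. For the stimulated guide contrast it recovered 49.3, 67.2 and 86.4% over 13301 genes, with 8 unchanged genes called. For the interaction it recovered 26.9, 56.7 and 74.2% over 13301 genes, with 4 unchanged genes called. For the slope between the CIT responses, simulated slopes of 0.8 and 1 came back as 0.826 and 0.993.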

Results

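RNA was measured in 12 libraries of CH12F3-2A cells, a mouse B cell lymphoma line that carries IgM and can switch to IgA in culture. Cells received a plasmid with Cas9 and either a guide against Nop16 (sgNop16) or a non-targeting guide (sgCtr), and were selected with puromycin for 72 h. They were then left unstimulated or given CIT, a mixture of 1 μg/ml anti-CD40L, 20 ng/ml IL-4 and 1 ng/ml TGF-β, for 24 h. Each of the 4 groups had 3 libraries, stated to be biological replicates. Total counts per library lay between 38866418 and 48615177. The study asks what NOP16, a nucleolar protein, does in class switch recombination to IgA. A gene is called here where its adjusted p was under 0.05 in edgeR's quasi-likelihood test over 16794 genes. The first principal component held 40.8% of the variance and separated stimulated from unstimulated libraries. The second held 7.2%, with all sgCtr libraries above all sgNop16 libraries. Where 5 or fewer members of a list were called, members outside the naming rule are also named, and these were chosen after their values were seen. Beside overlaps given with the values, Bax, Eif4a1, Ell2, Iglc2, Parp1, Pdia4, Rpl3, Rps20, Top2a and mt-Nd1 share annotated exons with another gene on the same strand. Atf5, Ccnd2, Cd72, Cdk4, Cdkn1a, Ciita, Dusp1, Dusp5, Ell2, Gins2, Idi1, Junb, Nfkb2, Npm3, Nusap1, Plek, Rgs16, Rpl10a, Runx1, Shmt2, Simc1, Stat5a, Tigar, Txndc5, mt-Co1 and mt-Nd5 share them with one on the opposite strand.

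Nop16 mRNA (ENSMUSG00000025869) was lower in sgNop16 than in sgCtr cells in both states, and most of it remained. It stood at 85.7 ± 3.10 against 106.3 ± 2.35 CPM (SD, n = 3) without CIT and at 65.7 ± 0.930 against 77.1 ± 3.46 CPM with CIT. The log2 differences were -0.31 ± 0.04 (SE, adjusted p = 0.000109) and -0.23 ± 0.05 (adjusted p = 0.00204). Every sgNop16 library lay below every sgCtr library of the same state. CIT itself lowered Nop16, by log2 changes of -0.46 ± 0.04 in sgCtr and -0.38 ± 0.05 in sgNop16 cells. The guide's position in the gene is not given in the sources used here, and an edited allele can keep its mRNA, so the level does not measure the share of edited cells. No group had a guide against another site. The guide differences below, those of p53 targets among them, therefore cannot be assigned to Nop16 alone.

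Among the heavy chain constant genes, Ighg3 and Ighm were lower with the Nop16 guide in both states. Ighg3 was at 5.96 ± 0.756 against 10.9 ± 0.693 CPM without CIT (log2 difference -0.87 ± 0.12) and at 24.6 ± 2.33 against 37.9 ± 4.88 CPM with CIT (-0.63 ± 0.11). Ighm, the µ gene, was at 2204 ± 23.9 against 2530 ± 13.1 CPM (-0.20 ± 0.02) and at 2129 ± 42.4 against 2279 ± 51.3 CPM (-0.10 ± 0.02). Igha, the α gene, was at 874 ± 14.7 against 957 ± 13.6 CPM without CIT (-0.13 ± 0.02, adjusted p = 0.00106). With CIT it was at 949 ± 10.1 against 999 ± 26.4 CPM (-0.07 ± 0.02), which was not called (adjusted p = 0.0537, between 0.00504 and 0.287 over the other settings). It was called with the stricter filter, library totals, counts divided by 4, only the stimulated libraries in the fit or DESeq2, and without sgCtr_CIT library 1 (adjusted p = 0.0458). Ighg2b was higher in sgNop16 cells after CIT, at 166 ± 8.77 against 130.0 ± 1.77 CPM (0.35 ± 0.07, adjusted p = 0.00333). Its unstimulated difference of 0.13 ± 0.10 was not called, nor were those of Ighg2c and Ighd in either state or of Ighg1 and Ighe after CIT. The Ighg2c difference with CIT was 0.45 ± 0.17 (adjusted p = 0.137, between 0.0156 and 0.365 over the other settings), and was called with counts divided by 4 and with only the stimulated libraries in the fit. The γ genes resemble one another in sequence, so how reads were divided between them is uncertain, and counts of Ighm and Igha do not separate switched from germline transcripts. No heavy chain constant gene was called for a different CIT response between the guides. Ighm came closest (difference of log2 responses 0.10 ± 0.03, adjusted p = 0.0529, between 0.0217 and 0.224 over the other settings). For Ighg2b it was 0.22 ± 0.12 (adjusted p = 0.448), and 0.35 without sgCtr_no library 3, where it was called (adjusted p = 0.0377).

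**Figure D1:**
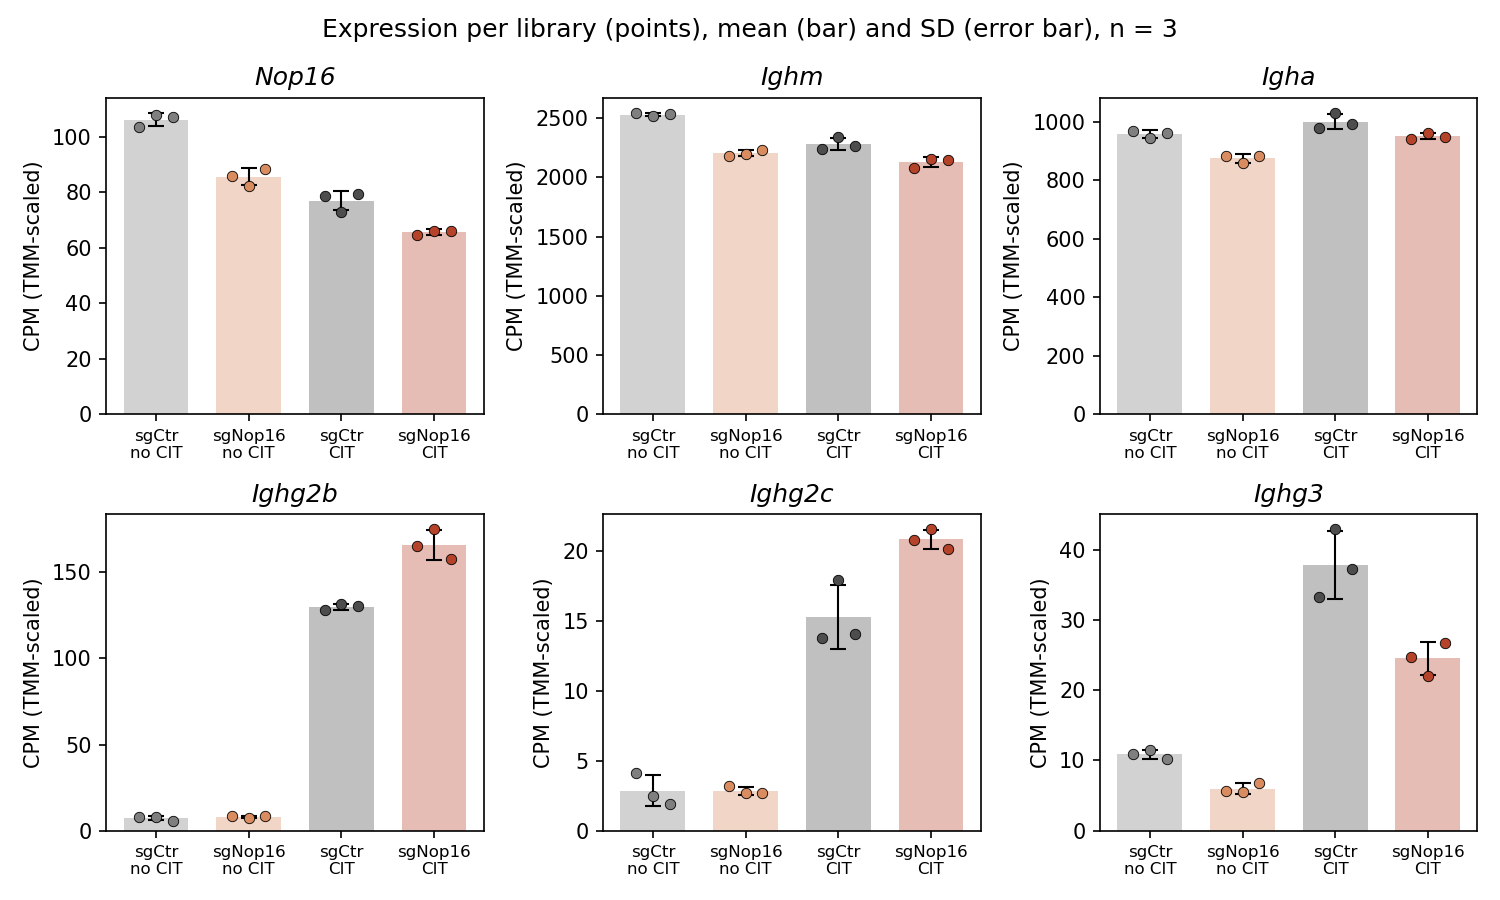
Levels in CPM (counts scaled to library size) of Nop16 and 5 heavy chain constant genes in the 4 groups, with each library as a point, the mean as a bar and the SD as the error bar (n = 3). Nop16 means run from 106.3 CPM in unstimulated sgCtr to 65.7 CPM in stimulated sgNop16 libraries, and Ighg2b reaches 166 CPM in stimulated sgNop16 against 130.0 CPM in stimulated sgCtr libraries.

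In sgCtr cells, CIT raised the γ and ε constant genes together with targets of all 3 stimuli. Ighg2b rose 18.1-fold, Ighg2c 5.40-fold and Ighg3 3.48-fold. Ighg1 was at least 140-fold and Ighe at least 20.1-fold higher, against a floor of 12 counts over the group. Ighd rose by 0.85 ± 0.11 and Ighm fell by 0.15 ± 0.02 on the log2 scale. Igha changed by 0.06 ± 0.02 (adjusted p = 0.0326), a call that ended without sgCtr_no library 2 or 3 or sgCtr_CIT library 2 or 3 (adjusted p up to 0.254) or without a low-count filter (0.112). Of 12 immunoglobulin chain genes 7 rose and 4 fell (7 and 4 adjusted over the list alone), the falls being Iglc1, Jchain, Iglc2 and Ighm. In all, 7007 genes were called, 3456 higher and 3551 lower, and 1407 of them differed at least 2-fold, 1072 higher and 335 lower. The larger share of all calls was higher with RLE size factors (3518 and 3486), library totals in place of TMM (3815 and 3163) and DESeq2 (3922 and 3719).

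Other large rises in sgCtr cells were those of Adamtsl2 (at least 488-fold), Lrig1 (at least 157-fold), Inava (at least 146-fold), Mpzl2 (at least 67.9-fold) and Vcam1 (at least 56.6-fold). Spsb1 rose 277-fold, Vdr, the vitamin D receptor gene, 118-fold and Tnni1 72.4-fold. Falls ranked highest by size, among genes with at least 5 CPM in the higher group and no overlap between the libraries of the groups, were those of Exosc6 (log2 change -5.34), C4bp (-5.27), Cd22 (-4.50), which encodes an inhibitory co-receptor of B cells, Il10 (-4.10), Pou2f3 (-4.03) and Pde2a (-4.00). Plk2 (-3.68), Il12a (-3.11), Gnat3 (-3.06) and Ehf (-3.01) followed. Exosc6 and Pde2a share annotated exons with other genes on the same strand, and Lrig1, Inava, Mpzl2, Vcam1, Spsb1 and Cd22 with a gene on the opposite strand. The call of Exosc6 ended in 5 of the 6 fits that left out a library (adjusted p up to 0.0712). That of Pde2a ended without sgCtr_no library 1 or sgCtr_CIT library 1 (adjusted p up to 0.063), where its change ranged from -7.19 to -3.42, and with only the sgCtr libraries in the fit (0.0619), and DESeq2 gave no adjusted p for it.

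Of 23 tested IL-4 and STAT6 targets 18 rose and 1, Il2rg, fell (19 and 1 adjusted over the list alone), with Cish, a feedback inhibitor of cytokine signalling, at 5.63 ± 0.18 and Il4i1, whose exons overlap Nup62, at 3.03 ± 0.14. Of 27 TGF-β and SMAD targets 20 rose and 1, Runx1, fell (20 and 1 adjusted over the list alone). Of 27 CD40 and NF-κB targets 20 rose and 3, Plek, Nfkbid and Birc3, fell (20 and 4 adjusted over the list alone), with Ccl22, a chemokine, at 2.31 ± 0.03 and Plek at -1.44 ± 0.03. Of 32 regulators of germline transcription 18 rose and 4, Prdm1, Runx1, Smad3 and Ets1, fell (19 and 4 adjusted over the list alone), with Stat5a at 2.95 ± 0.05, Id2 at 2.55 ± 0.09 and Prdm1 at -2.26 ± 0.23. Here and below, the name of this list is short for a list that also holds other transcription regulators of B cells. Of 30 interferon response genes 11 rose and 2, Bst2 and Irgm1, fell (11 and 2 adjusted over the list alone), with Oasl2 at 2.36 ± 0.35. The call of Irgm1 ended in 4 of the 6 fits that left out a library (adjusted p up to 0.182) and under 4 other settings (up to 0.0965). Camera adjusted p was 3.27e-57 for IL-4, 6.21e-27 for TGF-β, 2.36e-17 for CD40, 1.12e-07 for the regulators, 0.000632 for interferon and 0.000353 for immunoglobulin chains. These lists kept their calls with adjusted p = 2.43e-05, 0.000214, 0.000677, 0.0252, 0.0377 and 0.0377 with an estimated correlation.

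CIT lowered genes of ribosome production, MYC targets and cholesterol synthesis genes in sgCtr cells. Of 79 ribosome biogenesis genes 73 fell and 1, Ubtf, rose (73 and 1 adjusted over the list alone), with Ddx21, a nucleolar helicase, at -0.76 ± 0.03 and Nolc1 at -0.74 ± 0.03. Of 30 MYC targets 27 fell and 2, Ccnd2 and Hk2, rose (27 and 2 adjusted over the list alone), Myc itself going from 455 ± 6.49 to 198 ± 7.43 CPM. Of 24 cholesterol synthesis genes 19 fell and 1 rose (20 and 1 adjusted over the list alone). Camera adjusted p was 7.14e-21, 9.04e-13 and 5.73e-06, and adjusted p = 0.00527, 0.0252 and 0.0106 with an estimated correlation. The list calls that were lost were those of the integrated stress response (2 higher and 13 lower of 22, adjusted p = 0.0883 with an estimated correlation), S phase (15 lower of 30, 0.0627), B cell identity (14 higher and 10 lower of 30, 0.0739), p53 targets (18 higher and 5 lower of 33, 0.0882), immediate early genes (11 higher and 4 lower of 22, 0.17) and ribosomal proteins (1 higher and 41 lower of 78, 0.495). Adjusted over the list alone, these 6 lists had 2 higher and 13 lower, 15 lower, 14 higher and 12 lower, 19 higher and 5 lower, 11 higher and 5 lower, and 1 higher and 44 lower. The members that went against their list were Ddit4 and Atf5 in the stress response, Plk2, Tigar, Bax, Aen and Rps27l among p53 targets, Myc, Dusp5, Nr4a1 and Dusp1 among immediate early genes, and Rps20 among ribosomal proteins. The call of Atf5 ended without sgCtr_no library 2 or sgCtr_CIT library 2 (adjusted p up to 0.0639), and that of Dusp1 in 1 of the 6 fits that left out a library (0.0597). Ciita, the MHC class II transactivator gene, rose by 2.69 ± 0.03 and Bank1 fell by 2.83 ± 0.13 within the B cell list. Of 51 genes of the switch recombination machinery 7 rose and 21 fell (7 and 23 adjusted over the list alone), with Lig4, the ligase of end joining, at -2.28 ± 0.17, and the list was not called (adjusted p = 0.268).

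**Figure D2:**
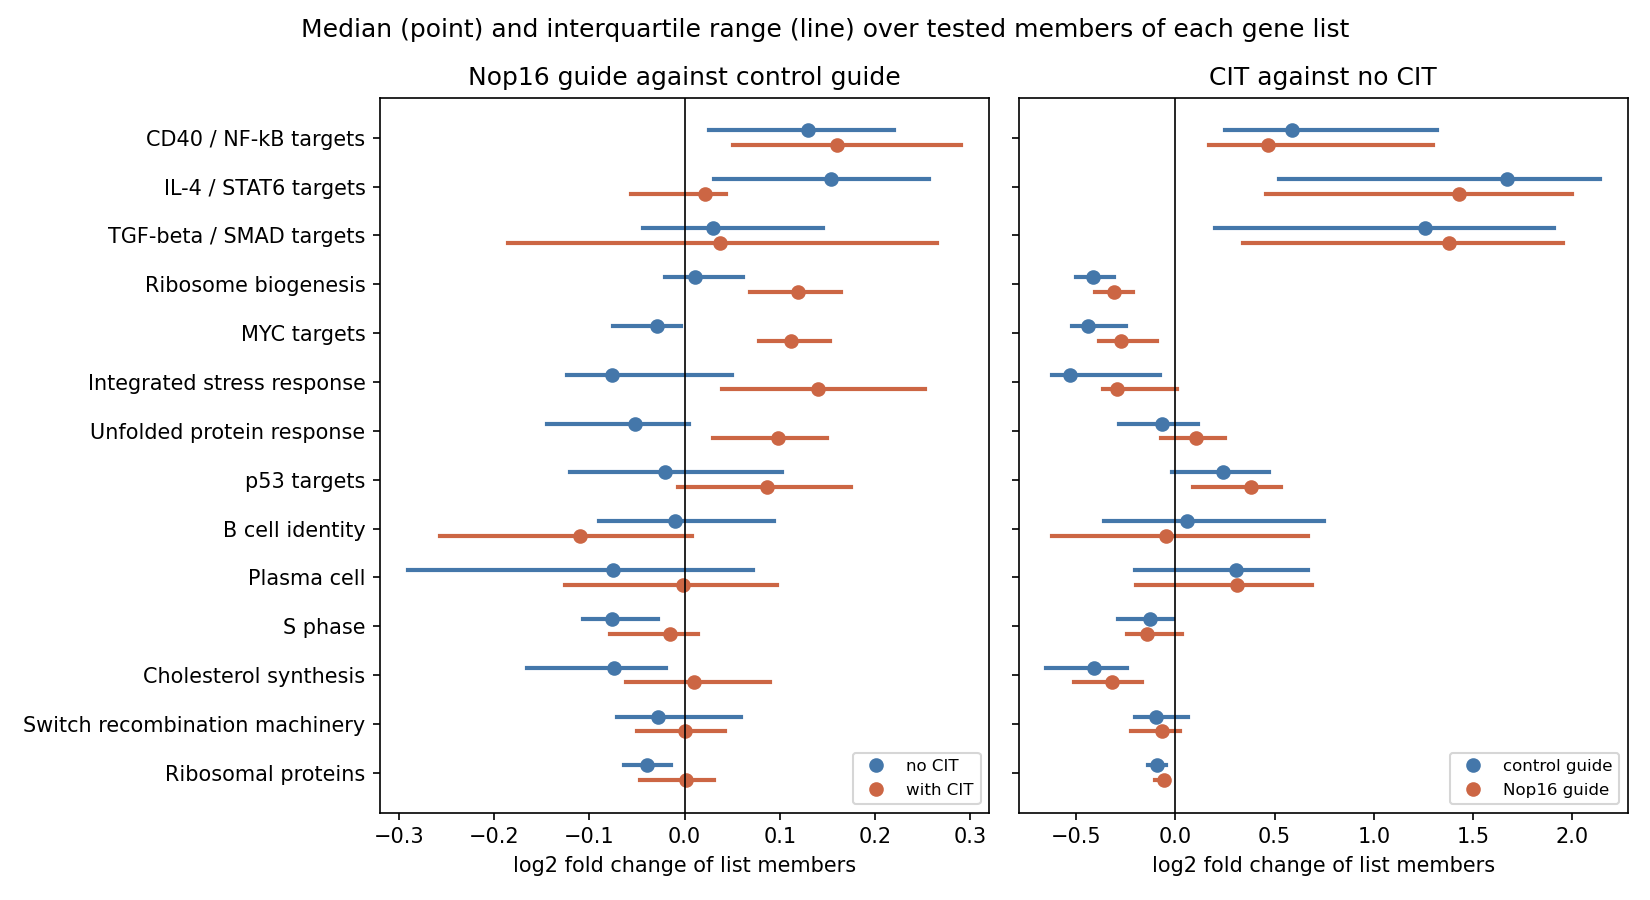
Median log2 fold change (point) and interquartile range (line) over the tested members of 14 gene lists, for the Nop16 guide against the control guide on the left and for CIT against no CIT on the right. Ribosome biogenesis members have a median of -0.42 with CIT in sgCtr and -0.31 in sgNop16 cells, and of 0.12 for the guide comparison with CIT.

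In sgNop16 cells CIT raised Ighg2b 21.1-fold, Ighg2c 7.33-fold and Ighg3 4.12-fold, with Ighg1 at least 165-fold and Ighe at least 22.6-fold higher. Igha rose by 0.12 ± 0.02. Ighm changed by -0.05 ± 0.02 (adjusted p = 0.0482), a call that ended without sgNop16_no library 3 or sgNop16_CIT library 1 and under 6 other settings (adjusted p up to 0.2). In all, 6343 genes were called, 3239 higher and 3104 lower, and 1256 differed at least 2-fold, 895 higher and 361 lower. Adamtsl2 (at least 455-fold), Lrig1 (at least 254-fold), Vcam1 (at least 120.0-fold), Smyd1 (at least 69.2-fold), Inava (148-fold), Spsb1 (90.4-fold), Vdr (64.1-fold) and Rgs16 (56.1-fold) were among the largest other rises with at least 5 CPM in the higher group and no overlap between libraries. The largest falls within these limits were in Pou2f3 and Cd22 (log2 change -5.07 for each), Plk2 (-4.12), Il10 (-3.84), Gnat3 (-3.58), Snai3 (-3.29), Pstpip2 (-3.27), Ehf (-3.27), Wnt16 (-3.25) and Endou (-3.17).

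Of the lists in sgNop16 cells, IL-4 targets had 18 rises and 1 fall, TGF-β targets 20 and 1, CD40 targets 21 and 3, the regulators of germline transcription 17 and 5, immunoglobulin chains 8 and 4, and interferon genes 10 and 1. Adjusted over the list alone these were 18 and 1, 22 and 1, 22 and 3, 17 and 5, 8 and 4, and 10 and 1. The falls were those of Il2rg among IL-4 targets, Runx1 among TGF-β targets, Plek, Nfkbid and Cd83 among CD40 targets, Prdm1, Smad3, Ets1, Runx1 and Hoxc4 among the regulators, Iglc1, Jchain, Iglc2 and Ighm among immunoglobulin chains and Irgm1 among interferon genes. Of 33 p53 targets 22 rose and 3, Plk2, Aen and Bax, fell (23 and 3 adjusted over the list alone), with Phlda3 at 2.28 ± 0.12. Ribosome biogenesis genes had 73 falls and 1 rise, of Ubtf, and cholesterol genes 17 falls and 2 rises, Idi1 among them, with the same counts adjusted over the list alone. Camera adjusted p for these 9 lists in this order was 1.67e-48, 9.78e-29, 8.35e-16, 1.71e-06, 5.9e-06, 0.00051, 0.00171, 1.17e-13 and 0.000316. They kept their calls, with adjusted p = 2.43e-05, 0.000124, 0.000677, 0.0313, 0.0253, 0.0326, 0.0225, 0.012 and 0.0225 with an estimated correlation. MYC targets had 24 falls and 2 rises, of Ccnd2 and Hk2 (25 and 2 adjusted over the list alone), a list call that was lost (adjusted p = 0.0886 with an estimated correlation). The call of plasma cell genes, with 10 rises and 5 falls of 17 (10 and 5 adjusted over the list alone), was lost too (adjusted p = 0.0531 with an estimated correlation), as were those of S phase (0.112), integrated stress response (0.318) and immediate early genes (0.2). The plasma cell genes that fell were Prdm1, Eaf2, Jchain, Txndc5 and Ell2. The call of Cd83 ended without sgNop16_CIT library 2 (adjusted p = 0.0551), and that of Eaf2 in 1 of the 6 fits that left out a library (0.0685).

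Over the 8325 genes with a mean CIT response across both guides, the total least squares slope of the sgNop16 on the sgCtr response was 0.95 ± 0.24 (jackknife SE over libraries). Slopes with 1 library left out lay together by the group that lost it. They were 0.859 to 0.883 for unstimulated sgCtr and 0.926 to 0.933 for stimulated sgCtr. For sgNop16 they were 1.045 to 1.075 without and 0.984 to 1.016 with CIT. The SE thus mixes a shift by group with the spread of libraries and does not measure that spread alone. Pearson's r across the 8325 genes, which are not independent replicates, was 0.848. Of the 5197 genes called in both responses, 5175 changed in the same direction.

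**Figure D3:**
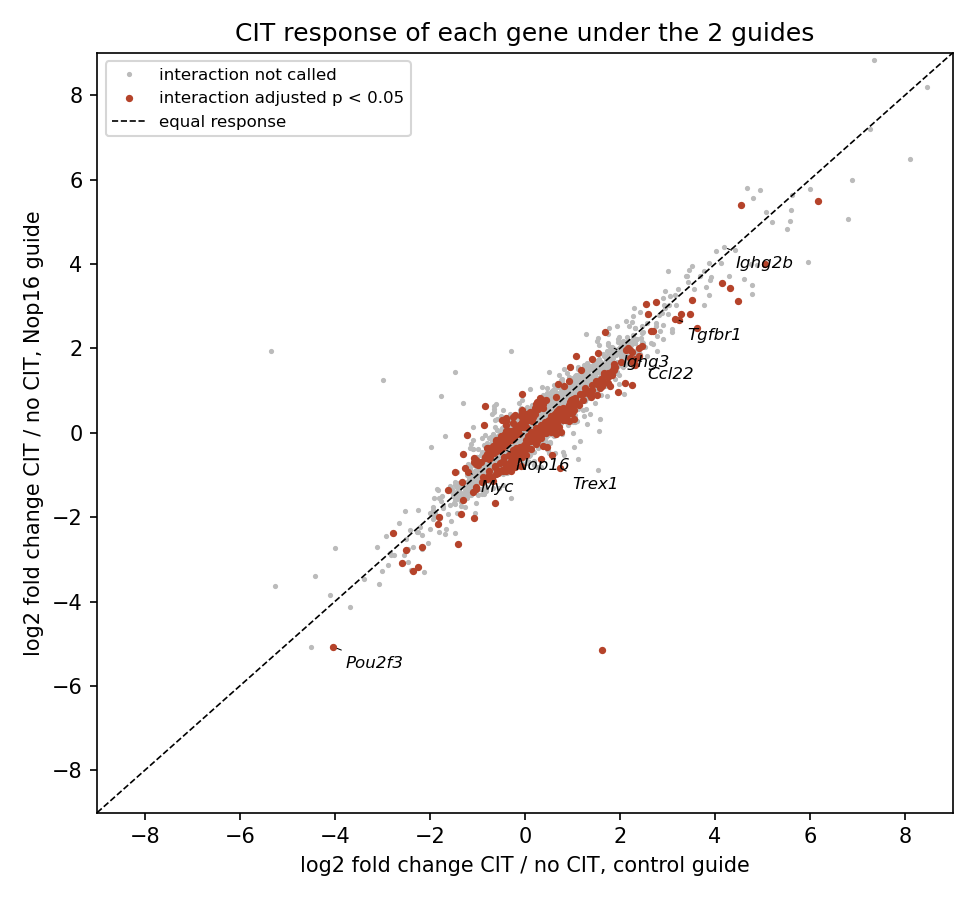
Log2 fold change with CIT in sgNop16 cells (vertical) against sgCtr cells (horizontal) for 10585 genes with a mean of at least 5 CPM in the highest group, with 464 genes called for a different response in red and the line of equal response dashed; 4 genes lie outside the axes. Ccl22 and Tgfbr1 rose less in sgNop16 cells, and Myc fell less. The level of Ccl22 was higher in sgNop16 than in sgCtr cells in both states.

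Before stimulation, sgNop16 cells had higher levels of CD40 and IL-4 target genes, MHC class II genes among them, and lower levels of immunoglobulin chain, S phase, plasma cell and cholesterol synthesis genes. Ccl22, a chemokine gene that is both a CD40 and an IL-4 target, was at 1169 ± 19.2 against 577 ± 17.4 CPM (2.02-fold, adjusted p = 8.69e-18). Of 27 CD40 targets 11 were higher and 0 lower (15 and 0 adjusted over the list alone), with Bcl2a1d, a survival gene of the BCL2 family, at 0.70 ± 0.05. Of 23 IL-4 targets 10 were higher and 0 lower (11 and 1 adjusted over the list alone), with H2-Eb1, an MHC class II chain gene, at 0.41 ± 0.03. Of 12 immunoglobulin chain genes 5 were lower and 0 higher, namely Ighg3, Jchain (-0.55), Iglc1 (-0.52), Ighm and Igha (5 adjusted over the list alone). Of 30 S phase genes 8 were lower (9 lower and 1 higher adjusted over the list alone), with the transcription factor E2f2 at -0.44 ± 0.07. Of 17 plasma cell genes 4 were lower, namely Jchain, Creb3l2 (-0.46), Xbp1 (-0.29) and Mzb1 (-0.17) (6 lower and 1 higher adjusted over the list alone). Of 24 cholesterol genes 3 were lower, Fdps (-0.24) and Insig1 (-0.23) among them (6 adjusted over the list alone). Camera adjusted p for these 6 lists in this order was 2.37e-25, 5.3e-24, 0.00017, 5.73e-06, 0.00173 and 0.000226. They kept their calls, with adjusted p = 0.000124, 0.000124, 0.0377, 0.0185, 0.0255 and 0.0228 with an estimated correlation. The macrophage marker Adgre1 was higher in the same libraries, at 0.319 ± 0.165 CPM against 0 in each sgCtr library (adjusted p = 0.00216).

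In unstimulated cells 682 genes were called, 360 higher and 322 lower, and 446 higher and 233 lower with library totals in place of TMM. Without sgCtr_no library 1 or 2 or sgNop16_no library 1 or 2 the lower genes numbered 184, 189, 186 and 198, with 295, 290, 274 and 302 higher. The median size of a called difference was 0.23 on the log2 scale, and 47 genes differed at least 2-fold, 41 higher and 6 lower. Among genes with at least 5 CPM in the higher group and no overlap between the libraries of the groups, the largest rises were in Fdx1l (1.97 ± 0.44), the chemokine genes Ccl3 (1.33 ± 0.30) and Ccl4 (1.03 ± 0.26), Tbc1d4 (1.21 ± 0.10), Synpo (1.10 ± 0.22), Arhgef40 (1.07 ± 0.12), Ccl22 (1.02 ± 0.03), Lilrb4a (0.93 ± 0.23), Nrgn (0.85 ± 0.21) and Gpr34 (0.75 ± 0.19). Within the same limits, the largest falls were in Ccpg1 (-0.99 ± 0.15), Ighg3, Pak6 (-0.87 ± 0.21), Vsir (-0.84 ± 0.13), Iglc3 (-0.77 ± 0.10), Fads2 (-0.72 ± 0.09), Bhlha15 (-0.72 ± 0.18), Padi3 (-0.69 ± 0.18), Fndc9 (-0.68 ± 0.14) and Ppp1r3b (-0.67 ± 0.09). Fdx1l, Ccpg1, Lilrb4a, Mzb1 and Fdps share annotated exons with another gene on the same strand, and Arhgef40 and Iglc3 with one on the opposite strand. Leaving out single libraries ended the calls of Fdx1l, Iglc1 and Insig1 in each of 6 fits, and those of Ccl3, Ccl4, Lilrb4a, Nrgn, Gpr34, Pak6, Bhlha15, Padi3, Jchain and Fdps in 2 to 5 of them (adjusted p up to 0.197). The calls of Fdx1l and Insig1 also ended with the replicate number as a block, and that of Fdx1l without a low-count filter (adjusted p up to 0.0743).

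Other lists in unstimulated cells were called lower but lost that call. These were the unfolded protein response (3 of 22, Xbp1, Sel1l and Pdia4, adjusted p = 0.0739 with an estimated correlation), mitosis (4 of 30, Aurkb, Nusap1, Mki67 and Top2a, 0.091), ribosomal proteins (5 of 78, Rps16, Rpl3, Rps6 and Rpl10a among them, 0.345), mitochondrially encoded genes (2 of 13, mt-Nd1 and mt-Co1, 0.263) and glycolysis (0 of 28, 0.381). Adjusted over the list alone 7, 4, 11, 5 and 0 members were lower. Of the glycolysis genes, none of which edgeR called, 5 had an unadjusted p under 0.05 and DESeq2 called 2. The integrated stress response, with Ddit3 and Atf5 higher and Shmt2 and Phgdh lower of 22, was called lower and lost that call too (2 higher and 8 lower adjusted over the list alone; adjusted p = 0.389 with an estimated correlation). Immediate early genes were called higher, with Egr2 at 0.63 and Egr1 at 0.53 higher and Btg2 at -0.30 lower of 22 (6 and 1 adjusted over the list alone), and lost that call (adjusted p = 0.0812 with an estimated correlation). Of 51 switch recombination genes 2 were higher and Parp1 lower (2 and 1 adjusted over the list alone), and the list was not called (adjusted p = 0.336). Of the members named for these lists, Xbp1, Sel1l, Egr1, Egr2, Btg2 and Parp1 kept their calls in all 6 fits that left out a library, and the other members lost theirs in 1 to 6 of them (adjusted p up to 0.163). Nusap1, Top2a, Atf5, Phgdh, Rps6, Rpl10a, mt-Nd1 and mt-Co1 were also not called under 1 to 3 of the other settings (adjusted p up to 0.0928).

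Some lists were not called without CIT. Of 79 ribosome biogenesis genes Rrp12 (0.18), Npm3 (0.14) and Utp20 (0.14) were higher and Fbl (-0.13) lower (adjusted p = 0.385). Of 30 MYC targets Ccnd2 (0.28) and Odc1 (0.16) were higher and Shmt2, Cdk4, Ptma and Eif4a1 lower (adjusted p = 0.12). Of 30 B cell identity genes 6 were higher, with Cd72 at 0.42, and Pou2af1, Ms4a1, Cd79b and Syk lower (adjusted p = 0.236). Of 27 TGF-β targets 3 were higher, Ccr6 (0.65) and Bcl2l11 (0.33) among them, and Id2 (-0.42) lower (adjusted p = 0.0786). Of 32 regulators of germline transcription Irf8 (0.20) and Nfkb2 (0.16) were higher and Id2 and Ets1 lower (adjusted p = 0.953). These 5 lists had, adjusted over the list alone, 4 higher and 3 lower, 2 and 5, 7 and 5, 4 and 1, and 2 and 4. Rrp12, Npm3, Utp20, Fbl, Shmt2, Cdk4, Ptma, Eif4a1, Pou2af1, Ms4a1, Cd79b, Syk and Ccr6 lost their calls in 2 to 6 of the 6 fits that left out a library (adjusted p up to 0.19). Npm3, Fbl, Eif4a1, Ms4a1, Cd79b, Syk, Ccr6 and Id2 were also not called under 1 to 5 of the other settings (adjusted p up to 0.188).

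After CIT, sgNop16 cells had higher levels of ribosome biogenesis, MYC target, CD40 target, unfolded protein response and p53 target genes than sgCtr cells, and lower levels of B cell identity genes. Of 79 ribosome biogenesis genes 34 were higher and 1, Ubtf (-0.10), lower (49 and 1 adjusted over the list alone), with the processing factor Rrp12 at 0.38 ± 0.05 and the RNA polymerase I subunit gene Polr1b at 0.29 ± 0.04. Of 30 MYC targets 18 were higher and 0 lower (25 and 0 adjusted over the list alone), with Myc at 245 ± 5.95 against 198 ± 7.43 CPM and Ccnd2, a cyclin D gene, at 0.40 ± 0.05. Of 27 CD40 targets 13 were higher and 2 lower (18 and 2 adjusted over the list alone), with the chemokine genes Ccl17 (1.33 ± 0.33) and Ccl22 (0.46 ± 0.02) higher and Rel (-0.38 ± 0.03) and Cd83 (-0.18 ± 0.05) lower. Of 22 unfolded protein response genes 7 were higher and 1, Xbp1 (-0.13), lower (9 and 1 adjusted over the list alone), with the chaperone gene Hyou1 at 0.29 ± 0.03. Of 33 p53 targets 9 were higher and 3 lower (11 and 3 adjusted over the list alone), with the cell cycle inhibitor gene Cdkn1a (0.73 ± 0.12) and Sesn2 (0.51 ± 0.07) higher and Plk2 (-0.77 ± 0.19), Trp53inp1 (-0.59 ± 0.13) and Btg2 (-0.54 ± 0.06) lower. Of 30 B cell identity genes 9 were lower and 2, Cd5 (0.23) and Cd72 (0.15), higher (15 and 4 adjusted over the list alone), with Ms4a1, which encodes CD20, at 192 ± 1.64 against 278 ± 4.09 CPM and Cd38 at -0.77 ± 0.16. Camera adjusted p for these 6 lists in this order was 2.04e-19, 1.67e-14, 2.95e-09, 1.21e-05, 0.00318 and 2.04e-08. They kept their calls, with adjusted p = 0.00647, 0.022, 0.00279, 0.0389, 0.0255 and 0.0102 with an estimated correlation.

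In stimulated cells 1195 genes were called, 680 higher and 515 lower, with a median size of 0.22 on the log2 scale, and 40 differed at least 2-fold, 20 higher and 20 lower. Among genes with at least 5 CPM in the higher group and no overlap between the libraries of the groups, the largest rises were in the chemokine gene Ccl5 (1.27 ± 0.32), Arhgap31 (1.16 ± 0.16), the adhesion gene Vcam1 (1.08 ± 0.29), Tbc1d4 (1.04 ± 0.09), Emp1 (1.00 ± 0.24), Gja1 (1.00 ± 0.22), Mt2 (0.97 ± 0.20), Rangrf (0.84 ± 0.09), B9d1 (0.83 ± 0.21) and Havcr2 (0.78 ± 0.23). Within these limits, the largest falls were in the exonuclease gene Trex1 (-1.31 ± 0.24), Pstpip2 (-1.14 ± 0.05), Nxph4 (-1.08 ± 0.16), Ppp1r3b (-0.95 ± 0.09), Slc45a3 (-0.92 ± 0.14), Bcl2l14 (-0.89 ± 0.22), Adamts14 (-0.87 ± 0.11), Wipf3 (-0.85 ± 0.06), Zfp831 (-0.83 ± 0.16) and Rab37 (-0.81 ± 0.15). Trex1 and Slc45a3 share annotated exons with another gene on the same strand, and Vcam1, Mt2, Rangrf, Pstpip2, Bcl2l14 and Wipf3 with one on the opposite strand. The calls of Ccl5, Vcam1, Emp1, B9d1, Havcr2, Bcl2l14, Ccl17, Cd83, Ubtf, Xbp1, Plk2 and Cd72 ended in 2 to 6 of the 6 fits that left out a library (adjusted p up to 0.18), and those of Vcam1, Havcr2, Cd83, Ubtf, Plk2 and Cd72 also under 1 to 3 of the other settings (up to 0.0939). Without sgNop16_CIT library 2 the count of called genes was 777, with 412 higher, and without sgCtr_CIT library 3 or sgNop16_CIT library 3 the higher genes numbered 449 and 451.

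Other list calls in stimulated cells were lost. The integrated stress response had 12 genes higher and 1, Ddit4, lower of 22 (12 and 1 adjusted over the list alone; adjusted p = 0.0531 with an estimated correlation). The regulators of germline transcription had 5 higher, Relb, Irf4, Nfkb2, Runx3 and Nfkb1, and 7 lower, led by Id3 at -0.45, of 32 (6 and 8 adjusted over the list alone; adjusted p = 0.199 with an estimated correlation). Glycolysis had 3 higher, Hk2, Eno1 and Ldha, of 28 (7 and 1 adjusted over the list alone; adjusted p = 0.389 with an estimated correlation). IL-4 targets were not called (2 higher, Ccl22 and Il2rg, of 23, adjusted p = 0.47), nor were TGF-β targets (4 higher, Cdkn1a, Junb and Runx3 among them, and 3 lower, Id3, Tgfbr1 and Bcl2l11, of 27, 0.531) or the switch recombination machinery (1 higher of 51, 0.613). Adjusted over the list alone these had 2 higher and 1 lower, 8 higher and 6 lower, and 1 higher. The calls of Nfkb1, Runx3, Hk2, Ldha, Il2rg and Bcl2l11 ended in 1 to 5 of the 6 fits that left out a library (adjusted p up to 0.232), and that of Hk2 also with only the stimulated libraries in the fit (0.0595).

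Lists that were lower without CIT were not all called with it. Of 12 immunoglobulin chain genes Ighg2b and Igkc (0.19) were higher and Iglc1 (-0.75), Ighg3, Jchain and Ighm lower (adjusted p = 0.565). Of 30 S phase genes E2f2 (-0.31), Gins2 (-0.21) and Uhrf1 (-0.083) were lower (adjusted p = 0.0722), and of 17 plasma cell genes Irf4 (0.18) and Mzb1 (0.11) were higher and Jchain, Creb3l2 (-0.29), Sec11c (-0.14) and Xbp1 lower (adjusted p = 0.448). Of 30 mitosis genes Mki67 was lower (adjusted p = 0.335), and of 13 mitochondrially encoded genes mt-Nd5 (adjusted p = 0.0568). Of 78 ribosomal protein genes Rplp0 was higher and 5 lower, Rpl9, Rpl22, Rpl3 and Rps4x among them (adjusted p = 0.61). These 6 lists had, adjusted over the list alone, 3 higher and 5 lower, 4 lower, 2 and 4, 1 lower, 2 lower, and 1 and 5. The test of the difference between the states called none of the S phase, plasma cell, mitosis and mitochondrial lists (adjusted p = 0.0722, 0.0953, 0.18 and 0.0833). Jchain, E2f2, Gins2, Uhrf1, Mzb1, Creb3l2, Sec11c, Xbp1, Mki67, mt-Nd5, Rpl9, Rpl22 and Rps4x lost their calls in 1 to 6 of the 6 fits that left out a library (adjusted p up to 0.23). Gins2, Uhrf1 and Rps4x were also not called under 1 or 2 of the other settings (adjusted p up to 0.092).

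The effects of the guide in the 2 states, which share no library, overlapped for some genes. In both states 114 genes were higher and 100 lower, against 14.6 and 9.9 for independent lists of these sizes. In opposite directions 27 were called, for which no such number was taken. The numbers 14.6 and 9.9 treat all tested genes as equally likely to be called. They may be too low, since low genes are harder to call in either state. Tbc1d4, Ccl22 and Pmaip1, a p53 target that promotes cell death (0.58 ± 0.05 and 0.49 ± 0.05), were higher in both. Ighg3, Ppp1r3b, Jchain and Ets1 (-0.29 ± 0.03 and -0.33 ± 0.03) were lower in both. The call of Jchain with CIT ended in 4 of the 6 fits that left out a library (adjusted p up to 0.0803). Across all 16794 genes, which are not independent replicates, Pearson's r of the log2 differences was 0.054 and Spearman's rho 0.115. Over genes with at least 5 CPM in 3 libraries r was 0.277. Of the 1636 genes called in either state, 67.9% had the same sign.

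The CIT response differed between the guides for 475 genes, 207 with a more positive and 268 with a more negative change in sgNop16 cells, and 138 and 327 with library totals in place of TMM. Of these, 436 also had a mean CIT response across both guides, which was smaller in sgNop16 cells for 307 and larger for 129. Ribosome biogenesis and MYC target genes fell less in sgNop16 cells, and IL-4 targets rose less. The IL-4 targets rose from a higher level, with a median guide difference of 0.15 without and 0.021 with CIT. For ribosome biogenesis genes it was 0.011 without and 0.12 with CIT, and for MYC targets -0.029 and 0.11. Myc fell by 1.21 ± 0.03 in sgCtr and by 0.92 ± 0.03 in sgNop16 cells, and Ccl22 rose by 2.31 in sgCtr cells with a difference of -0.56 ± 0.03 between the guides. Of 79 ribosome biogenesis genes 11, of 30 MYC targets 13, of 22 unfolded protein response genes 8 and of 22 integrated stress response genes 9 had a more positive change, and none a more negative one. Of 33 p53 targets Psrc1, Sesn2 and Rps27l, and 2 of 24 cholesterol genes, Idi1 among them, also had a more positive change. Adjusted over the list alone these were 21, 22, 15, 13, 4 and 3, with 1 more negative in the integrated stress response. IL-4 targets (9 of 23), CD40 targets (5 of 27, Ccl22, Rel, Bcl2a1d, Bcl2l1 and Cd86) and B cell identity genes (7 of 30) had more negative changes. Adjusted over the list alone these were 9, 8 and 13, with 4 CD40 targets and 1 B cell gene more positive. Camera adjusted p for these 9 lists in this order was 4.67e-12, 3.6e-15, 1.23e-11, 2.34e-09, 0.00803, 0.0017, 1.61e-12, 0.00311 and 4.55e-09. They kept their calls, with adjusted p = 0.0191, 0.0202, 0.0102, 0.0313, 0.0355, 0.0355, 0.000826, 0.0377 and 0.0084 with an estimated correlation. For the CD40 list the mean difference was 0.032 and the median -0.014, so the mean differs in sign from the test. Without sgNop16_no library 1 or sgNop16_CIT library 2 the count of genes was 305 or 306, with 100 and 126 more positive and 205 and 180 more negative. Without sgCtr_no library 1, 2 or 3, sgCtr_CIT library 2 or 3, or sgNop16_no library 2 or 3 the more positive genes numbered 122, 127, 133, 137, 134, 124 and 132. The calls of Sesn2, Idi1, Bcl2l1 and Cd86 ended in 1 to 9 of the 12 fits that left out a library (adjusted p up to 0.0743).

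Markers of other cell types were few or low. Of 16 T cell, 18 macrophage, 14 fibroblast and 9 erythroid markers, 5, 4, 3 and 5 were tested. Lck, listed as a T cell marker, had group means between 186 and 211 CPM and was lower with the Nop16 guide after CIT (-0.12 ± 0.04), a call that ended in 5 of the 6 fits that left out a library (adjusted p up to 0.188), without a low-count filter and with the replicate number as a block (up to 0.0667). Without CIT its difference was 0.12 ± 0.04 and was not called (adjusted p = 0.0669, between 0.0129 and 0.272 over the other settings, and 0.0182 without sgCtr_no library 3). Of 4 macrophage markers 1, Adgre1, was higher with the Nop16 guide without CIT (2 adjusted over the list alone), at least 3.39-fold against the floor. It rose at least 7.45-fold with CIT in sgCtr cells, and its CIT response was more negative in sgNop16 cells (adjusted p = 0.0195), with group means under 1 CPM. Itgam fell at least 8.06-fold with CIT in sgCtr cells, from 0.704 ± 0.368 CPM. Csf1r rose with CIT in both guides (2.48 ± 0.27 and 2.40 ± 0.26), and its guide differences were not called without CIT (0.85 ± 0.28, adjusted p = 0.0938, between 0.0267 and 0.425 over the other settings, the lowest without sgNop16_no library 3) or with it (0.77 ± 0.24, adjusted p = 0.0545, between 0.0103 and 0.237). Itgam and Lck share annotated exons with another gene on the same strand and Csf1r with one on the opposite strand. The T cell and erythroid lists were not called in either guide comparison (adjusted p = 0.0722 and 0.253 without and 0.512 and 0.652 with CIT), and the other 2 lists had too few members for the test.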

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

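The tests of stimulated RNA, of a weaker response of every gene and of reads shared between the γ genes were chosen only after the results were seen. The second of these was run on 2 choices of genes, the other choice being made after the first value was known, and its comparison of quartiles was added when all of them were known.

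The CIT response differed between the guides for 475 genes. Guide labels were reassigned within each state in 100 of 200 possible splits, and 2 of the 100, the real one included, gave as many genes. The highest other count was 1398, from the split that is the real one with the guide labels swapped in 1 state, which turns a guide effect common to both states into an interaction. The 214 genes called the same way in both guide comparisons were reached by 1 of the 100 splits, the real one, with 27 as the highest other value. Such splits also mix libraries that differ by guide within a group, which adds to the spread, so few calls in them follow from any guide effect and neither count tests the difference of responses or the overlap by itself. For the single contrasts only 10 splits of 6 libraries exist, too few for a share under 0.05. In fits of those 6 libraries alone, the real and highest other counts were 547 and 2 for the guide without CIT, 1163 and 3 with CIT, 6888 and 0 for CIT in sgCtr and 6233 and 0 in sgNop16 cells, with 1 split as large in each.

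The lists whose CIT response differed by the test of the difference had these median log2 differences: immunoglobulin chains 0.16, regulators of germline transcription -0.022, CD40 targets -0.014, IL-4 targets -0.16, ribosome biogenesis 0.11, ribosomal proteins 0.031, p53 targets 0.082, MYC targets 0.15, integrated stress response 0.20, unfolded protein response 0.15, B cell identity -0.15, glycolysis 0.11, cholesterol synthesis 0.092 and T cell markers -0.14. The calls of 5 of them were lost, with adjusted p = 0.204 for immunoglobulin chains, 0.284 for the regulators, 0.526 for ribosomal proteins, 0.165 for glycolysis and 0.171 for T cell markers with an estimated correlation. Of the ribosomal proteins edgeR called 0, with 16 at an unadjusted p under 0.05 and 4 called by DESeq2, and the list was not called with library totals either (adjusted p = 0.214).

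Single genes with a more positive CIT response in sgNop16 cells, by the test of the difference, were Ppp1r3e (1.15), Il2ra, a chain of the IL-2 receptor (1.06), Ccpg1 (0.98), Susd2 (0.85), Fndc9 (0.80), Rangrf (0.78), Pgbd5 (0.76), Prrg4 (0.75), Trp73 (0.70) and Fads2 (0.68). More negative responses were those of Trex1 (-1.57), Abca5 (-1.37), Ipcef1 (-1.14), Zfp811 (-1.14), Echdc3 (-1.11), Scel (-1.07), Hes3 (-1.05), Pou2f3 (-1.04) and Hmcn2 (-0.98). Trex1 and Ccpg1 share annotated exons with another gene on the same strand, and Rangrf, Trp73 and Ipcef1 with one on the opposite strand. Leaving out 1 library ended the calls of Ppp1r3e, Il2ra, Fndc9, Pgbd5, Abca5, Zfp811, Scel, Hes3 and Hmcn2 in 4 to 9 of 12 fits (adjusted p up to 0.182). Susd2, Abca5 and Scel were also not called with counts divided by 4 (adjusted p up to 0.229), nor Scel, Hes3 and Hmcn2 with the replicate number as a block (up to 0.068) or Hmcn2 without a low-count filter (0.0545).

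List members with a more positive response were Igkc (0.21), Id2 (0.51), Rrp1b (0.22), Mrto4 (0.25), Sesn2 (0.45), Psrc1 (0.48), Rps27l (0.30), Mthfd1 (0.29), Myc (0.29), Cth (0.55), Hyou1 (0.39), Herpud1 (0.29), Mzb1 (0.28), Parp1 (0.14), Pkm (0.13) and Idi1 (0.23). Those with a more negative response were Irf8 (-0.52), Rel (-0.46), Id3 (-0.45), Hoxc4 (-0.38), Ccl22 (-0.56), Bcl2a1d (-0.44), Bcl2l1 (-0.34), Cd86 (-0.21), H2-Eb1 (-0.39), Tgfbr1 (-0.46), Bcl2l11 (-0.52), Blk (-0.41), Ms4a1 (-0.41), Egr2 (-0.53), Egr1 (-0.51), Btg1 (-0.46) and Lck (-0.24). The macrophage marker Adgre1 had a fitted difference of -6.40, which is no measure of its size, since all 3 unstimulated sgCtr libraries were at 0. Mzb1, Parp1, Pkm and Lck share annotated exons with another gene on the same strand, and Rrp1b, Mthfd1 and Idi1 with one on the opposite strand. The calls of Id2, Mrto4, Sesn2, Herpud1, Parp1, Pkm, Idi1, Bcl2l1, Cd86 and Egr2 ended in 1 to 11 of the 12 fits that left out a library (adjusted p up to 0.173), and those of Id2, Mrto4, Parp1, Pkm and Egr2 also under 1 to 4 of the other settings (up to 0.102).

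CD40 and IL-4 targets were higher in unstimulated sgNop16 libraries, as if some stimulated RNA were present. The 18 called members that CIT raised would need a median of 14.69% of stimulated RNA (quartiles 11.86 and 24.98%). They were picked as higher in this same comparison, which favours a high share. The 57 other genes that CIT raised at least 8-fold were not picked so, and allow 0.76% (quartiles -0.19 and 2.16%). Stimulated cells or RNA carried over at a larger share would have raised these genes too. Their values argue against such a carry-over as the cause. Removing a GC and length trend from each library shifted the tested genes by a mean absolute 0.008 on the log2 scale, against a median of 0.254 over the 20 called members (0.252 after it, with both lists still called), so that trend was too small to account for them. An effect of the Nop16 guide on these genes before stimulation may remain as a hypothesis. Differences between the transfected cultures other than the guide were not tested.

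Ribosome biogenesis and MYC target genes fell less with CIT in sgNop16 libraries, and a GC and length trend did not account for it, since its removal shifted the tested genes by a mean absolute 0.023 and moved the median over 109 members from 0.12 to 0.109, the members called from 24 to 22, and left both lists called (adjusted p = 1.72e-11 and 6.6e-14). The ratio of the log2 CIT responses, sgNop16 over sgCtr, had a median of 0.717 over the 100 members that fell (quartiles 0.622 and 0.796), and 0.945 over 59 genes raised at least 8-fold in sgCtr cells (0.833 and 1.035). It was 0.956 over 63 such genes chosen on the mean response of both guides (0.827 and 1.058). Over 21 TGF-β targets that rose it was 1.008 (0.813 and 1.082). The quartiles of these raised genes lie above those of the list members that fell. That comparison was chosen with all quartiles known. A CIT response weakened by a common ratio in every gene would put these raised genes near 0.717. For the genes covered, the values argue against it as the whole cause. The ratio was not taken over IL-4 and CD40 targets. Their median log2 responses were 1.672 and 0.59 in sgCtr and 1.427 and 0.469 in sgNop16 cells. The ratio was 0.929 over all 4241 genes that rose (0.681 and 1.206) and 0.841 over 3984 others that fell (0.599 and 1.146). These ranges overlap that of the list members. A bound of 0.95 set for the median of the 8-fold genes was passed under 1 choice and missed under the other. A weaker CIT response of every gene thus stays open as part of the cause. An effect of the guide on these lists stays among the open explanations.

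Ighg3 was lower in sgNop16 libraries, and reads shared between the γ genes stay open as a possible explanation. Without CIT the loss was 4.915 CPM and the other γ genes together gained 0.593 CPM (SE 1.371). That gain is under the 2.458 CPM that would have favoured shared reads, while its upper limit of 3.281 CPM is above it, so they are not excluded either. With CIT the loss was 13.306 CPM (SE 3.12) and the gain 43.789 CPM (SE 5.577). Reads moved from Ighg3 could not supply a gain larger than its loss, so part of that gain is separate. Whether the loss is an effect of the guide on Ighg3 or of shared reads cannot be told at these counts.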

How the results depend on the processing

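Library totals without TMM, counts divided by 4 and the comparison over genes called in either guide contrast were chosen only after the data were seen. Counts of called genes stayed within 1.5 times under RLE size factors, the replicate block, no low-count filter, the stricter filter, library totals, counts divided by 4 and only the groups compared. DESeq2 called 1209, 1958 and 1029 genes for the guide without CIT, the guide with CIT and the interaction; the cause was not tested. Of the genes called by edgeR, DESeq2 called 98.4, 99.2 and 99.6% in these contrasts, none in the opposite direction. With a minimum of 1.5-fold the counts were 109 (79 higher and 30 lower), 118 (52 and 66), 2482 (1707 and 775), 2194 (1463 and 731) and 57 (18 and 39) for the 5 contrasts, since fewer genes can pass. The larger share thus turned from higher to lower for the guide with CIT and from lower to higher for CIT in sgCtr cells. Leaving out 1 library gave 460 to 515 genes for the guide without CIT, 777 to 899 with CIT (777 without sgNop16_CIT library 2), 6436 to 6527 and 5707 to 5804 for CIT in sgCtr and sgNop16 cells, and 305 to 389 for the interaction (305 without sgNop16_no library 1 and 306 without sgNop16_CIT library 2), with fewer samples in each fit.

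Nop16 kept its direction and call in each fit, at -0.34 to -0.28 and -0.27 to -0.21 for the guide and -0.49 to -0.43 and -0.42 to -0.37 for CIT when 1 library was left out. The response slope then ranged from 0.859 to 1.075, and its r, 0.826 to 0.851, became 0.96 with the stricter filter and 0.941 with counts divided by 4, where fewer low genes enter. The r of the 2 guide effects, 0.027 to 0.069 without 1 library, was 0.014 without a filter, 0.277 with the stricter one, 0.158 with counts divided by 4 and 0.191 over genes called in either (Spearman 0.439). Of 65 list calls 39 held with an estimated correlation, while fry called 75, losing 6 and gaining 16. RLE factors and library totals gave 64 each. For the guide without CIT, the estimated correlations ran from -0.005 for p53 targets to 0.73 for mitochondrially encoded genes. Where an estimate is above the preset 0.01, the preset p is likely too small. Some lists with low estimates also lost calls, such as p53 targets with CIT in sgCtr cells (-0.002). The cause of those losses was not tested.

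Signs turned for genes that were not called: without CIT, Ighg2b went to -0.005 without sgCtr_no library 3 (up to 0.22 in the other fits), and Ighg2c fell below 0 without sgCtr_no library 2, sgCtr_no library 3 or sgNop16_no library 1 (range -0.207 to 0.36). With CIT, Ighe ranged from -0.016 without sgNop16_CIT library 1 to 0.322. Of the named called genes, 38 of 81, 49 of 84, 101 of 107, 97 of 107 and 34 of 53 in the 5 contrasts kept their calls without any 1 library, and none changed sign.

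With the replicate number as a block the counts were 617, 1117, 6932, 6247 and 407, the slope 0.943 and all 65 list calls were as before. The 18 pairs of libraries with the same number had correlated deviations of -0.045 to 0.023, and 1 of 12 libraries correlated best with its own number. These values show no pairing of the libraries by number. They do not tell whether the replicates were separate transfections. If they were not, the p-values of the guide comparisons measure only the spread between cultures of a transfection. Depth limits low genes most: Ighe and Ighg1 lay at the floor without CIT.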

Other observations

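The hypothesis tested in this part was fixed before its result was seen. Members outside the naming rule are named here too, and were chosen after their values were seen. Of 33 p53 targets, Pmaip1 was higher before CIT in sgNop16 cells, and Trp53inp1 (-0.61), Psrc1 (-0.38) and Btg2 (-0.30) were lower (2 and 3 adjusted over the list alone), and the list was not called (adjusted p = 0.795). Of 30 interferon response genes, Psmb9 (0.22) and Tap1 (0.17), both of antigen processing, were higher without CIT and 1 gene was higher with CIT (the same counts adjusted over the list alone), and the list was not called (adjusted p = 0.165 and 0.431). Psmb9 and Tap1 share annotated exons with each other on opposite strands. Of 22 immediate early genes after CIT, Fosl2 (0.61), Myc (0.31) and Junb (0.25) were higher and Btg2 (-0.54) and Btg1 (-0.32) lower (4 and 2 adjusted over the list alone), and the list was not called (adjusted p = 0.335). The calls of Trp53inp1, Tap1 and Fosl2 ended in 2 to 5 of the 6 fits that left out a library (adjusted p up to 0.141). Tap1 was also not called with only the unstimulated libraries in the fit (adjusted p = 0.121), nor Fosl2 without a low-count filter or with the replicate number as a block (up to 0.059).

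Of 24 cholesterol synthesis genes 2, Idi1 (0.21) among them, were higher after CIT in sgNop16 cells (3 adjusted over the list alone), and the list was not called (adjusted p = 0.733). Of 13 genes of PRC2 and H3K27 demethylases, edgeR called 0 for the guide without CIT, with 2 at an unadjusted p under 0.05 and 1 called by DESeq2. With CIT Aebp2 (0.16), a PRC2 subunit gene, was higher (2 higher and 3 lower adjusted over the list alone). CIT raised 3 and lowered 3 of them with each guide (5 and 3 in sgCtr and 3 and 3 in sgNop16 cells adjusted over the list alone). For the interaction edgeR called 0, with 4 at an unadjusted p under 0.05 and 1 called by DESeq2. The list was not called in any contrast (adjusted p = 0.128 and 0.566 for the guide without and with CIT, 0.953 and 0.771 for CIT in sgCtr and sgNop16 cells, and 0.518 for the interaction). The call of Aebp2 ended without sgCtr_CIT library 1 or sgNop16_CIT library 3 (adjusted p up to 0.0843). The median, mean and test differed in sign for some lists that were not called, namely regulators of germline transcription, B cell identity and p53 for the guide without CIT, and IL-4, switch machinery, ribosomal proteins and T cell markers with CIT. The same held for T cell markers with CIT in sgCtr cells, for B cell identity, mitosis, glycolysis and mitochondrial genes in sgNop16 cells, and for TGF-β and PRC2 in the interaction.

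A large deletion or silencing around the edited site could lower the genes beside Nop16. Of 20 neighbours, 10 on each side in the GRCm38 gene order, 13 were tested and edgeR called 0 lower with the guide in both states (0 at an unadjusted p under 0.05 and 0 by DESeq2). Their median log2 differences were -0.066 without and 0.024 with CIT, so most of the expression of these genes as a set remained. Without CIT 1 of them had an unadjusted p under 0.05. Arl10 and Higd2a lie next to Nop16 on either side. They were at -0.117 and -0.172 without and at 0.024 and -0.027 with CIT, and were not called. Nop16 itself changed by only -0.31 and -0.23. A like loss of neighbours in part of the cells could therefore go unseen and is not excluded. In stimulated cells Simc1, a neighbour, was higher with the guide (0.29, adjusted p = 0.0226), a call that ended without sgCtr_CIT library 1, sgCtr_CIT library 2 or sgNop16_CIT library 3 (adjusted p up to 0.165) and with only the stimulated libraries in the fit (0.0544).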
